A study of Mus musculus with 6 samples.

How the data were processed

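RNA-seq was made from extracellular vesicles of mouse trophoblast stem cells, 3 libraries from uninfected cells given phosphate-buffered saline and 3 from cells infected with Listeria monocytogenes. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with the Nextera XT kit. Per the submitters' processing notes, Trimmomatic, HISAT2, featureCounts and DESeq2 were used with the mm10 build. Their versions, the annotation, strand use, and the handling of reads with several alignments or duplicates are not given in the sources used here. The authors deposited whole-number counts of reads per gene, not normalized, in 1 table of 27179 genes.

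Genes were named by NCBI gene ID except 174 named by symbol. Of the IDs, 25101 matched a gene of the RefSeq GRCm38.p6 table and 1904 did not. Of the entries named by symbol, 165 matched and 9 carried a symbol whose ID had its own entry. Those 9 were tested but kept out of lists and of naming. Entries without a matched gene held 2.39% of counts. Exon length and GC content came from GENCODE vM21 on the same build, for 24865 entries. Coordinates are 1-based on GRCm38/mm10.

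Total counts ranged from 2974502 to 7114594 per library. Groups were taken from the labels, and the comparison, tests, the 32 gene lists tested and the naming rule were fixed before the data were examined. The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM factors and filterByExpr defaults, which kept 23900 genes, and Benjamini-Hochberg adjustment at 0.05. Standard errors are the log2 fold change divided by the square root of F. CPM values use TMM-scaled totals, except olfactory receptor CPM per kb of exon, which uses unscaled totals. DESeq2 1.42.0 was run beside it. Gene lists with at least 5 tested members, 32 of them, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which asks whether a list's genes move one way and does not compare them with other genes. Library measures were compared by exact two-sided permutation tests over 20 assignments, for which the smallest p is 0.1. Genes were counted as detected after thinning each library to 2974502 counts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

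The naming rule took the 10 higher and 10 lower genes with the largest log2 fold change among those past the threshold, of at least median level and with non-overlapping groups, leaving out predicted genes. Where fewer passed, it took the next by smallest unadjusted p under the same conditions, up to 5 in each direction, said not to have passed. It also took up to 4 members of each list by smallest unadjusted p, and the 10 genes of highest mean CPM in uninfected libraries. Of the up to 4 members, 2 per list are given, a number settled after the values were seen.

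The differential test was tested on 5 simulated data sets drawn from the means, dispersions and library sizes of the 23900 genes, each with 200 genes of at least median level changed. In these, camera called a list of 40 genes moved by a log2 change of -0.75 in 5 of 5 runs with the preset correlation and in 4 with an estimated one, and called 0 of 150 unchanged lists with the preset one. Each gene was simulated independently and the unchanged lists were random genes. The simulation therefore cannot say how often camera calls unchanged lists whose genes vary together. In the data the estimated correlation was 0.667 for ribosomal proteins and 0.198 for histones. No pair of libraries agreed within sampling noise, the chi-square per gene being at least 6.73.

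The tests were repeated with DESeq2's size factors, with library totals only, with mitochondrial genes left out, with DESeq2, with no filter, with a stricter filter, with the replicate number as a block, with robust dispersions, and with each library left out. The olfactory receptor level and the lists of sensory receptor, antigen receptor and keratin-associated genes were added after seeing the data. Settings added then were genes at least 5 times above the olfactory receptor level (7501 genes), a GC and exon length correction (22572 genes with both values), and fits without infected replicates 1 and 2, or without these and uninfected replicate 1. With 1 infected library left, the fit pools the spread and assumes that this library varies like the others. Interval bounds given for counts cover counting error only.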

Results

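The series holds RNA-seq counts from extracellular vesicles, the membrane-bound particles that cells release, collected from mouse trophoblast stem cells, the self-renewing precursors of the placental trophoblast. The comparison asked how the RNA in vesicles from cells infected with Listeria monocytogenes, a bacterium that can infect the placenta, differed from that in vesicles from uninfected cells given phosphate-buffered saline. There were 6 libraries, 3 in each group. Total counts were 5171833, 5548148 and 7114594 in the uninfected libraries and 2974502, 4606846 and 4237885 in the infected libraries. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

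In the uninfected libraries the genes with the highest CPM included structured noncoding RNAs, mitochondrial transcripts and long protein-coding genes. CPM is not scaled by gene length, so long genes rank higher than they would per base. Exon length was 28898 bases for Obscn and 18113 for Plec, against 319 for Rpph1. Among the 10 genes with the highest mean CPM, 2 matched no reference gene, with the identifiers 100861531 at 5467 ± 974 CPM and 667102 at 2310.4 ± 1655 CPM (SD, n = 3 here and below). Vaultrc5, a vault RNA, stood at 4046 ± 5513 CPM, with 10376 CPM in uninfected replicate 1 and 294 CPM in uninfected replicate 2. Ncl, encoding nucleolin, stood at 2176 ± 976 CPM. Rpph1, the RNA of ribonuclease P, stood at 1250.1 ± 773 CPM, and the mitochondrial ribosomal RNA mt-Rnr2 stood at 1009.5 ± 918 CPM. The others were mt-Nd6 at 945 ± 779 CPM, Plec, encoding the cytoskeletal linker plectin, at 856 ± 186 CPM, Obscn at 802 ± 56.2 CPM and Peg10, a retrotransposon-derived placental gene, at 752 ± 569 CPM. In infected libraries Plec stood at 389 ± 199.5 CPM, with an adjusted p of 0.298 in edgeR's quasi-likelihood test and 0.0248 in DESeq2. The other 9 had an adjusted p above 0.05 with both tools.

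Library composition overlapped between groups for the shares of counts. The 10 most abundant genes of each library took 1.94 ± 0.978% of counts in uninfected and 1.43 ± 0.751% in infected libraries (exact two-sided permutation p = 0.5). Mitochondrially encoded genes took 0.445 ± 0.299% and 0.415 ± 0.348% (exact permutation p = 0.9), and cytosolic ribosomal protein genes 0.564 ± 0.257% and 0.309 ± 0.176% (exact permutation p = 0.3). At equal depth, 23921 ± 1179.6 genes were detected in uninfected and 25501 ± 334 in infected libraries, with every infected library above every uninfected one (exact permutation p = 0.1, the smallest this design allows), and the difference of 1579 genes was 904 without uninfected replicate 1. Without uninfected replicate 1, the difference in the share of the 10 most abundant genes, infected minus uninfected, turned from -0.516 to 0.0476 percentage points. That of mitochondrially encoded genes turned from -0.0297 to 0.143 without uninfected replicate 1, to 0.0971 without infected replicate 2 and to 0.0421 without infected replicate 3.

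**Figure D1:**
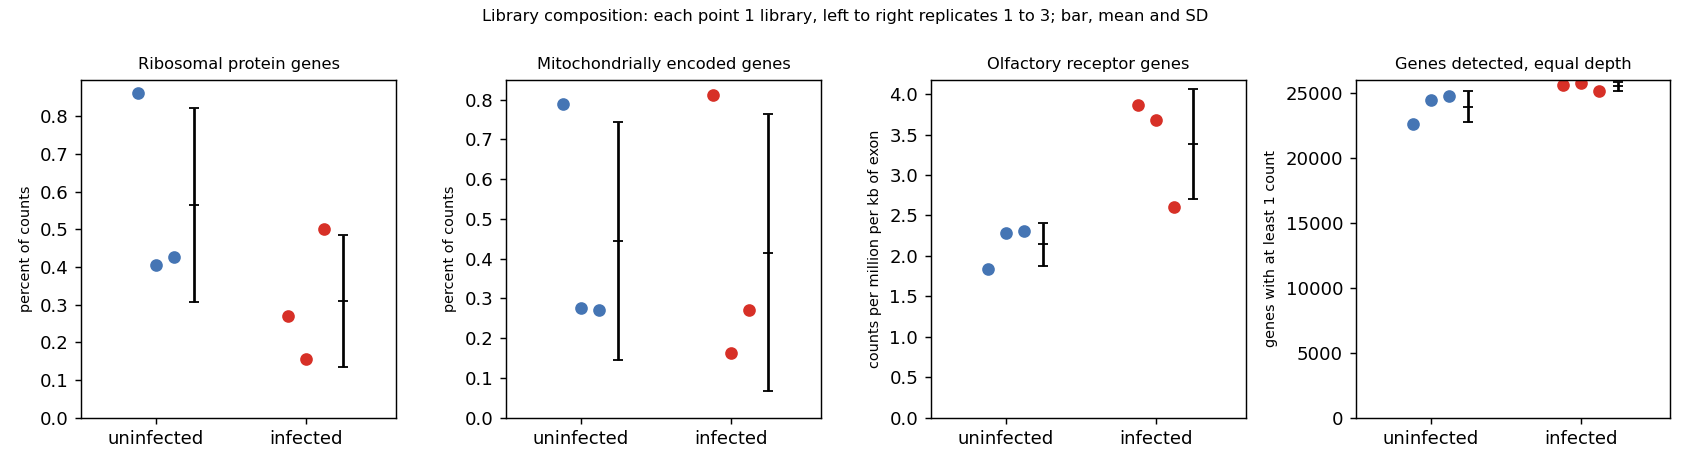
Percent of counts from ribosomal protein genes and from mitochondrially encoded genes, olfactory receptor CPM per kb of exon on unscaled totals, and genes with at least 1 count at equal depth, for each of the 3 uninfected and 3 infected libraries (points, replicates 1 to 3 from left to right) with group mean and SD (bars). Ribosomal protein shares overlapped between groups, at 0.564 ± 0.257% and 0.309 ± 0.176%, and all 3 infected libraries had more detected genes than the uninfected ones.

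Olfactory receptor genes, which are transcribed mainly in olfactory neurons, were counted in every library. On unscaled library totals they had 2.14 ± 0.264 CPM per kb of exon in uninfected and 3.38 ± 0.681 in infected libraries (exact permutation p = 0.1, the smallest possible). Levels of genes named below are given, where they are low, as multiples of this level averaged over the 6 libraries. The genes detected at 1 count or more, given above, may include genes counted only at this level, which was higher in infected libraries. Whether that accounts for the extra genes detected there was not tested. Mean Spearman correlation of log2 CPM across the 23900 tested genes, which are not independent replicates, was 0.855 within uninfected, 0.889 within infected and 0.831 between groups. The mean correlation within groups minus between groups, 0.0411, was the highest of the 10 splits of the libraries into 3 and 3 (permutation p = 0.1, the smallest possible). It was 0.00759 without infected replicate 1, 0.0163 without infected replicate 2 and 0.0741 without infected replicate 3. Infected replicates 1 and 2 correlated at 0.934, whereas infected replicate 3 correlated at 0.920 with uninfected replicate 2 and at 0.849 with infected replicate 1. Uninfected replicate 1 correlated at 0.830 and 0.834 with uninfected replicates 2 and 3, which correlated at 0.903 with each other. On the first principal component, which held 54.9% of the variance, uninfected replicate 1 lay at -189 and the other 5 libraries from -4.68 to 83.7.

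In infected vesicles, transcripts of cytosolic ribosomal proteins, replication-dependent histones, immediate early genes, glycolysis and the actin cytoskeleton were lower as groups, and differentiated trophoblast markers were higher as a group. Each of these calls was made by camera with a preset correlation of 0.01 and was lost with one estimated from the data (adjusted p = 0.340 to 0.352 with an estimated correlation). The median log2 fold change was -1.38 for histones, -0.96 for ribosomal proteins and 0.49 for differentiated trophoblast markers. Of 32 gene lists, 15 passed an adjusted p of 0.05 by camera with the preset correlation, 14 lower and 1 higher, and 0 passed with an estimated correlation or by fry. The count was 9 without uninfected replicate 1 and, in settings chosen after seeing the data, 22 after a correction for GC content and exon length (3 higher, 19 lower) and 9 among genes at least 5 times above the olfactory receptor level. Above that level 6 of the 15 lists did not pass, with medians of -0.22 for nuclear-encoded oxidative phosphorylation, -0.21 for endoplasmic reticulum stress and amino acid response, -0.46 for heat shock proteins, -0.14 for autophagy and lysosome, -0.14 for proteasome and 0.012 for differentiated trophoblast markers. TMM factors were computed anew on the genes kept in this setting, and every named gene kept there shifted upward. Trim71 went from -1.52 to -1.24, Actn1 from -0.86 to -0.57 and Obscn from -0.38 to -0.096. Medians above that level, here and below, are therefore not on the scale of the main fit. The 10 splits of the libraries into 3 and 3 were also compared, a test chosen after seeing the data. At least 15 lists passed in 3 of them, the real split included, and the highest count, 17, came from another split. The number of passing lists therefore does not set infection apart from other groupings of the libraries.

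Log2 fold changes of well-covered genes were lower at GC contents above 50% than below 46%. Among genes at least 5 times above the olfactory receptor level, the median log2 fold change was 0.10 at a GC content up to 40%, 0.081 from 43 to 46%, -0.25 from 50 to 55% and -0.46 from 55 to 60%. The median GC content of list members was 51.00% for ribosomal proteins, 58.1% for histones, 54.6% for immediate early genes, 52.9% for glycolysis and 52.2% for the actin cytoskeleton, which were lower, and 44.3% for differentiated trophoblast markers, which were higher. The Spearman correlation of counts with exon length across genes, which are not independent replicates, was 0.456, 0.475 and 0.494 in the uninfected and 0.620, 0.601 and 0.517 in the infected libraries.

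No single gene passed the threshold. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 23900 genes had an adjusted p under 0.05, the smallest adjusted p being 0.298, and 3136 genes had an unadjusted p under 0.05, of which 1414 were higher and 1722 lower. DESeq2's Wald test called 213 genes, 141 higher and 72 lower. With library totals in place of TMM factors the median log2 fold change of all genes shifted to 0.13, and edgeR's unadjusted split was 1940 higher and 1048 lower. After the GC and length correction that split was 540 higher and 1636 lower. Without infected replicate 1 the genes at unadjusted p under 0.05 numbered 1155 of 24237, and without infected replicate 2 they numbered 1231 of 24209. Both are near the share of 0.05 that unchanged genes alone would give, and 0 passed the adjusted threshold in each case. Without infected replicate 3 such genes numbered 4505 of 24644. Without uninfected replicates 1, 2 and 3 in turn they numbered 3591 of 24486, 3289 of 24457 and 3629 of 24423, and again 0 passed the adjusted threshold. On counts simulated for this comparison over 23900 genes, the changed genes were drawn only from those of at least median level. Over 5 runs edgeR called 8.96% (30 of 335) of genes changed 2 times, 77.9% (261 of 335) of those changed 4 times and 96.1% (317 of 330) of those changed 8 times, plus 44 unchanged genes. DESeq2 called 24.5% (82), 88.96% (298) and 98.5% (325), plus 241 unchanged genes, so its calls may hold more false ones than its threshold of 0.05 implies. Recovery of genes below median level was not simulated.

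Among genes of at least median level whose groups did not overlap, predicted genes left out, the 5 with the smallest p in each direction were taken, and none of these 10 passed edgeR's threshold (adjusted p = 0.298 for each). Ccdc83 (NCBI gene 75338, chromosome 7, 90223500 to 90265432 in GRCm38/mm10) had 14.1 ± 1.79 CPM in uninfected and 56.7 ± 18.8 CPM in infected libraries, a log2 fold change of 1.998 (SE 0.38). Ifi203 (NCBI gene 15950, chromosome 1, 173920400 to 173942866), of the interferon-inducible p200 family, had 12.3 ± 0.650 CPM in uninfected and 65.9 ± 42.7 CPM in infected libraries and a log2 fold change of 2.42 (SE 0.50). It has close paralogs, so its counts are uncertain. Lepr, the leptin receptor (NCBI gene 16847, chromosome 4, 101717137 to 101815352), had a log2 fold change of 1.80 (SE 0.38), and a separate entry carrying the Lepr symbol was not joined to it. Dmd, encoding dystrophin (NCBI gene 13405, chromosome X, 82814664 to 85205050), had 1.80 (SE 0.39), and Rp1, a photoreceptor gene (NCBI gene 19888, chromosome 1, 4115673 to 4409266), 1.94 (SE 0.43). In DESeq2 these 5 genes had adjusted p values of 0.00347 to 0.0134. After the GC and length correction the log2 fold changes were 1.51 for Ccdc83, 1.32 for Ifi203, 1.16 for Lepr, 0.96 for Dmd and 1.10 for Rp1.

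Trim71 (NCBI gene 636931, chromosome 9, 114511268 to 114564369), an RNA-binding ubiquitin ligase of early embryos, had 248 ± 31.7 CPM in uninfected and 86.1 ± 25.6 CPM in infected libraries and a log2 fold change of -1.52 (SE 0.27). Noxo1, an organizer of NADPH oxidase 1 (NCBI gene 71893, chromosome 17, 24696234 to 24700530), had 206 ± 83.9 CPM in uninfected and 60.2 ± 19.99 CPM in infected libraries and a log2 fold change of -1.78 (SE 0.34). The immediate early gene Ier5 (NCBI gene 15939, chromosome 1, 155096367 to 155099636) had -1.90 (SE 0.37), the mitochondrial carrier Slc25a28 (NCBI gene 246696, chromosome 19, 43663801 to 43675006) -2.01 (SE 0.42) and the matricellular gene Ccn1 (NCBI gene 16007, chromosome 3, 145646971 to 145649985) -1.87 (SE 0.39). In DESeq2 their adjusted p values were 0.000181 to 0.0153.

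Of the other genes named here, DESeq2 called Myh9, Actn1, Arf6, Sfpq, Syna, Prl3d1, Rhox5, Cldn3, Col5a2, H3c15, H1f2, Xist and Plec, with adjusted p values from 0.00142 to 0.0486, while edgeR called none of them (0 of 23900 genes by its adjusted p, 3136 at an unadjusted p under 0.05). After the GC and length correction Plec had -0.54, Xist 0.52 and Myh9 -0.81, from -1.14, 1.25 and -1.28, and of the 80 named genes with a corrected value 20 had a log2 fold change smaller by over 1.5 times, 4 larger by over 1.5 times and 3 of the other sign. Several named genes overlap another annotated gene, and strand use in counting is not given in the sources used here, so the counts of Ifi203, Trim71, Noxo1, Rpl13, mt-Co1, mt-Atp6, Ndufb5, Aldoa, Pkm, Nfkb2, Cgas, H2-Q4, Actn1, Arf6, Sfpq, Srsf2, Grn, Sqstm1, Psmd1, Gins2, Cdk4, Sox21, Syna, Igf2, Cldn3, Dab2, Rpph1, Malat1, Xist, Ncl, mt-Nd6, Plec and Obscn are uncertain. Levels under 2 times that of olfactory receptors were found for Casp4 0.473, Dmd 0.702, Fap 1.04, Xist 1.09, Rp1 1.10, Col5a2 1.20, Msmo1 1.42, Lepr 1.54, Prl3d1 1.62, Dab2 1.64, Ifi203 1.85 and Ifit2 1.86 times.

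**Figure D2:**
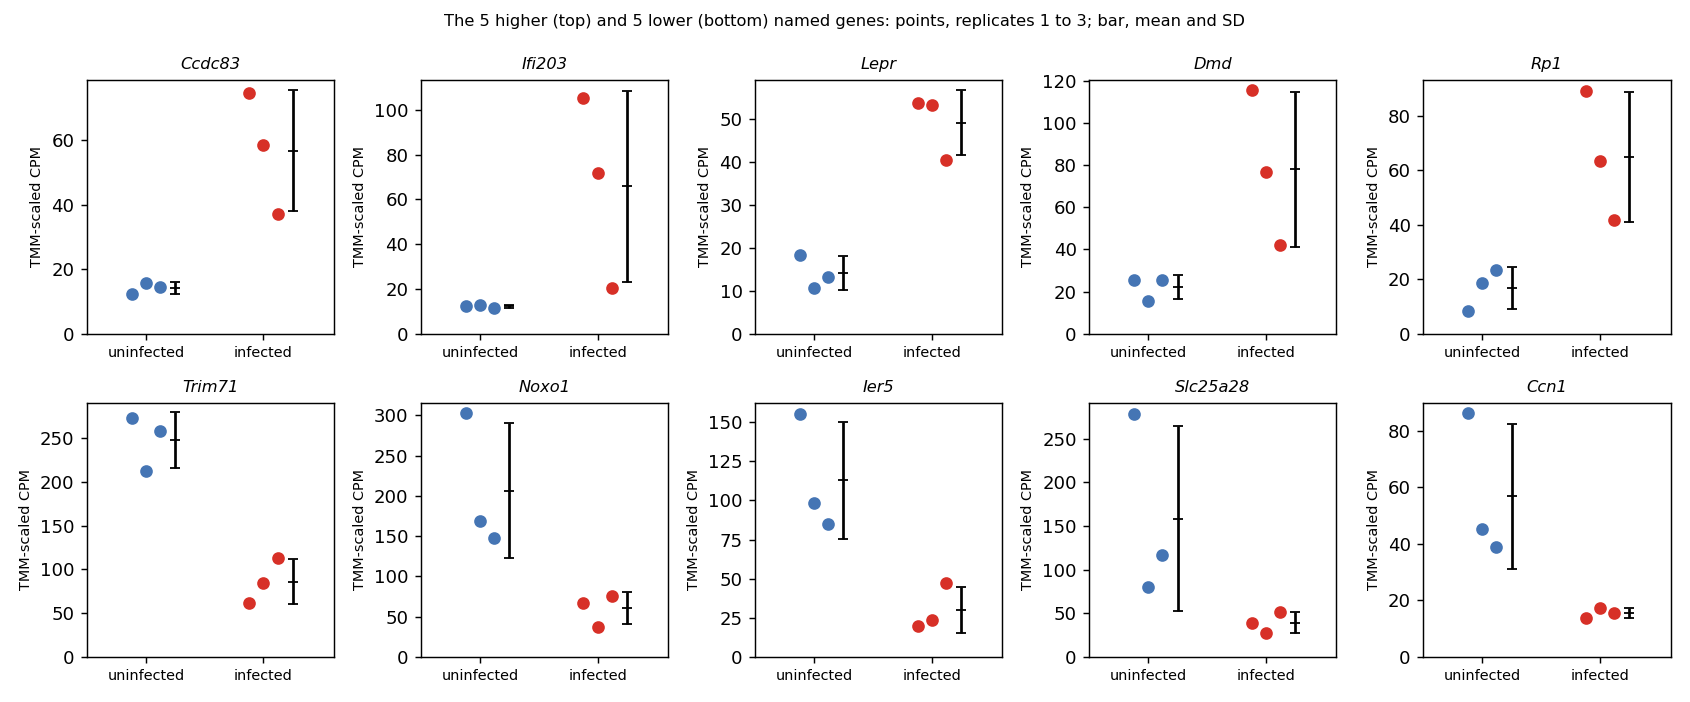
TMM-scaled CPM of the 5 higher (top row) and 5 lower (bottom row) genes in each library (points, replicates 1 to 3 from left to right) with group mean and SD (bars), each axis starting at 0. All 3 infected libraries lie on one side of the uninfected ones for each gene, which was a condition of the choice, and Ifi203 in infected libraries had 65.9 ± 42.7 CPM.

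For the lists, 0 members passed in edgeR when adjusted over all genes. Adjusted over the list alone, members passed in edgeR in 8 of the 32 lists, whose counts stand with each list below, and 0 passed in the other 24. DESeq2 adjusted the same way passed members in some of those 24, such as 6 lower in glycolysis, 3 lower in cell cycle and 3 higher in fibroblast markers. It also passed 14 lower histones, against 6 in edgeR.

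Transcripts of the translation machinery were lower as lists in infected vesicles, by camera with the preset correlation only. Of 79 tested cytosolic ribosomal protein genes, 78 had a negative log2 fold change, with a median of -0.96 (camera adjusted p = 1.14e-17; adjusted p = 0.352 with an estimated correlation). Infected replicate 3 stood apart, with 0.501% of counts from these genes against 0.270% and 0.156% in infected replicates 1 and 2 and 0.860%, 0.406% and 0.425% in uninfected replicates 1, 2 and 3. Rpl13 had 30.4 ± 6.07 CPM in uninfected and 9.84 ± 2.99 CPM in infected libraries, a log2 fold change of -1.63 (SE 0.46), and Rplp0 -1.59 (SE 0.48). Many of these genes have processed pseudogenes, so their counts are uncertain. Translation factors had a median of -0.59 over 37 genes (camera adjusted p = 9.65e-06; adjusted p = 0.395 with an estimated correlation), with Eif3f at -1.14 (SE 0.42) and Eef2, the translocation factor, at -1.03 (SE 0.38). The ribosomal protein median was -0.49 without uninfected replicate 1, -0.61 without infected replicate 2 and -1.46 without infected replicate 3, and that of translation factors -0.33, no longer past camera's threshold, without uninfected replicate 1 and -0.92 without infected replicate 3. Without infected replicates 1 and 2, a setting chosen after seeing the data, the medians were -0.22, still passing, and -0.11, not passing. With uninfected replicate 1 left out as well, they turned to 0.22 and 0.18, but these 3 libraries held the highest and the 2 lowest shares of ribosomal protein counts, so the turn of that list follows from the choice.

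Replication-dependent histone genes, whose mRNAs lack poly(A) tails, had the lowest median of the 32 lists. It was -1.38 over 54 genes, 48 of them below 0 (camera adjusted p = 3.12e-11; adjusted p = 0.340 with an estimated correlation). Adjusted over the list alone, 6 passed in edgeR, all lower. H3c15 had 43.3 ± 13.7 CPM in uninfected and 7.86 ± 1.31 CPM in infected libraries, a log2 fold change of -2.45 (SE 0.43) (edgeR adjusted p = 0.298, DESeq2 adjusted p = 0.00142), and H1f2 -2.05 (SE 0.51). Histone genes are near-identical copies, so single members are uncertain. With each library left out in turn the median lay between -1.77 and -1.11, past the camera threshold each time.

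Stress and growth response genes were lower as lists. Immediate early genes had a median of -0.61, with 28 of 29 below 0 (camera adjusted p = 2.26e-08; adjusted p = 0.340 with an estimated correlation), Ier5 and Ccn1 having the smallest p, and 2 genes passed lower when adjusted over the list alone. Genes of p53 targets and apoptosis had a median of -0.47 over 25 genes (camera adjusted p = 0.00106; adjusted p = 0.340 with an estimated correlation), with the apoptosis regulators Bbc3 at -1.24 (SE 0.37) and Mcl1 at -1.20 (SE 0.39). Endoplasmic reticulum stress and amino acid response genes had -0.37 over 34 (camera adjusted p = 0.00106; adjusted p = 0.340 with an estimated correlation), with Trib3 at -1.09 (SE 0.37) and Ddit4 at -1.38 (SE 0.47). Heat shock proteins had -0.57 over 18 (camera adjusted p = 0.00730; adjusted p = 0.395 with an estimated correlation), with Hspb8 at -1.09 (SE 0.38) and Bag3 at -0.75 (SE 0.28). Heat shock proteins no longer passed camera without uninfected replicate 1, at -0.17, or infected replicate 2, at -0.30, and had -0.97 without infected replicate 3 and 0.00046, not passing, without infected replicates 1 and 2. The median of p53 targets and apoptosis was -0.36, not passing, without uninfected replicate 1 and -0.73 above background, and that of immediate early genes -0.95 without infected replicate 3, -0.37 after the GC and length correction and -0.31 without infected replicates 1 and 2, where the list of endoplasmic reticulum stress and amino acid response had -0.17, both still passing.

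Metabolic, cytoskeletal and junction genes were also lower as lists. Glycolysis genes had a median of -0.46, with 20 of 22 below 0 (camera adjusted p = 2.58e-05; adjusted p = 0.340 with an estimated correlation), with Aldoa at -1.40 (SE 0.41) and the pyruvate kinase gene Pkm at -1.17 (SE 0.34). Nuclear-encoded oxidative phosphorylation genes had -0.63 over 69 genes (camera adjusted p = 0.000103; adjusted p = 0.340 with an estimated correlation), with Ndufb5 at -1.16 (SE 0.32) and Atp5g1 at -1.30 (SE 0.47). The actin cytoskeleton list had -0.45 over 43 genes (camera adjusted p = 9.26e-07; adjusted p = 0.340 with an estimated correlation). Its member Myh9, encoding non-muscle myosin IIA heavy chain, had 568 ± 172 CPM in uninfected and 234 ± 98.3 CPM in infected libraries, a log2 fold change of -1.28 (SE 0.32) (edgeR adjusted p = 0.298, DESeq2 adjusted p = 0.0129), and Actn1 -0.86 (SE 0.24). Epithelial keratins and junctions had -0.42 over 25 genes (camera adjusted p = 0.00114; adjusted p = 0.340 with an estimated correlation), with the claudins Cldn3 at -2.17 (SE 0.53) and Cldn4 at -1.49 (SE 0.45). Adjusted over the list alone, 3 actin and 4 junction genes passed, all lower. The median of nuclear-encoded oxidative phosphorylation was -0.29, and that of epithelial keratins and junctions -0.18, no longer passing camera, without uninfected replicate 1. The actin cytoskeleton had -0.79 and epithelial keratins and junctions -0.66 without infected replicate 3, and neither these (-0.094 and -0.055) nor nuclear-encoded oxidative phosphorylation (-0.22) passed without infected replicates 1 and 2.

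RNA-binding, lysosomal and proteasomal genes were lower as lists. RNA sorting and RNA-binding proteins had a median of -0.53 over 38 genes (camera adjusted p = 0.000325; adjusted p = 0.395 with an estimated correlation), with the splicing factors Sfpq at -1.43 (SE 0.33) and Srsf2 at -1.56 (SE 0.49), and 1 gene passed lower when adjusted over the list alone. Autophagy and lysosome genes had -0.30 over 44 (camera adjusted p = 0.00406; adjusted p = 0.340 with an estimated correlation), with Grn at -0.96 (SE 0.26) and the autophagy receptor gene Sqstm1 at -1.20 (SE 0.34). Proteasome genes had -0.42 over 31 (camera adjusted p = 0.0103; adjusted p = 0.413 with an estimated correlation), with Psmb3 at -0.99 (SE 0.33) and, in the other direction, Psmd1 at 0.77 (SE 0.26). RNA sorting and RNA-binding proteins no longer passed camera without uninfected replicate 1, at -0.19, and had -0.31 without infected replicate 2. The proteasome no longer passed without uninfected replicate 1, at -0.10, or infected replicate 2, at -0.29, and autophagy and lysosome genes had -0.20 without infected replicate 1 and -0.18 with library totals. None of the 3 passed without infected replicates 1 and 2, at -0.15, -0.12 and -0.18.

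Differentiated trophoblast markers were the list that camera with the preset correlation called higher. The median was 0.49, with 23 of 31 above 0 (camera adjusted p = 0.0268; adjusted p = 0.340 with an estimated correlation), and adjusted over the list alone 1 gene passed higher and 1 lower. Prl3d1, encoding a placental lactogen of trophoblast giant cells, had 2 counts in the uninfected and 98 in the infected libraries, a ratio per total count of 73.9 (exact 95% interval 19.9 to 619, counting error only). Infected replicates 1, 2 and 3 held 19, 15 and 64 of these counts. With the spread between libraries, the log2 fold change of Prl3d1 was 5.79 (SE 1.58) (edgeR adjusted p = 0.298, DESeq2 adjusted p = 0.0260). Syna, encoding the fusogenic syncytin-A of the labyrinth, had 133 ± 49.6 CPM in uninfected and 48.1 ± 13.8 CPM in infected libraries, a log2 fold change of -1.47 (SE 0.33) (edgeR adjusted p = 0.298, DESeq2 adjusted p = 0.0161). The list no longer passed without infected replicate 3, at 0.55, or with a stricter count filter, at 0.42, and had 0.99 without uninfected replicate 2. Among genes at least 5 times above the olfactory receptor level, a setting chosen after seeing the data, its median was 0.012. There the list did not pass and camera's direction turned to lower. After the GC and length correction its median was 0.24, passing. The list had a median GC content of 44.3%. In the main fit, all genes under 2 times the olfactory receptor level with a GC content of 43 to 46% had a median of 0.58. The list's median of 0.49 was thus no higher than that of such genes.

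**Figure D3:**
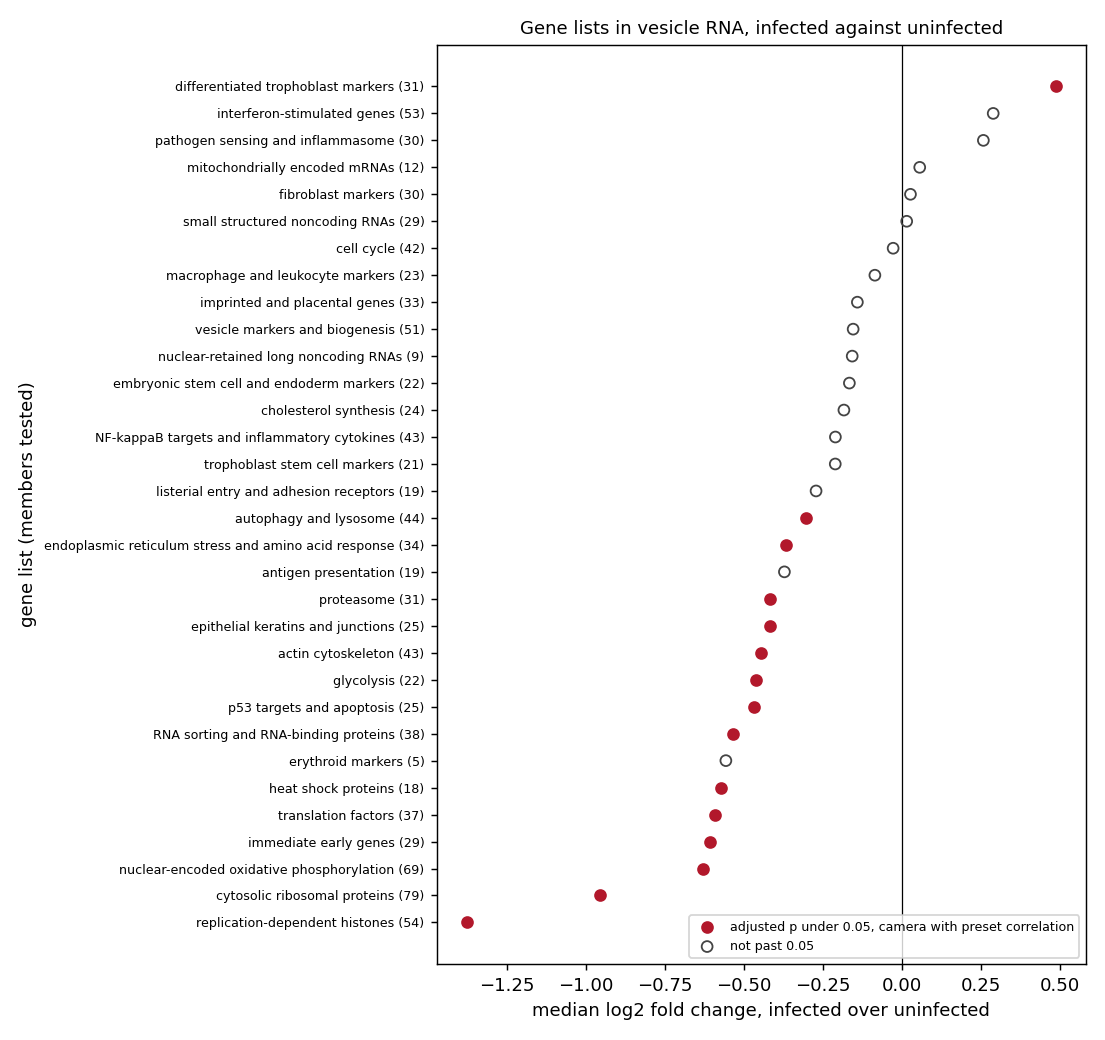
Median log2 fold change (x axis, infected over uninfected) of the 32 tested gene lists, with the number of tested members in brackets, filled where camera with a preset correlation gave an adjusted p under 0.05. The 14 filled lists to the left include histones at -1.38 and ribosomal proteins at -0.96, the 1 to the right is differentiated trophoblast markers at 0.49, and 0 lists passed with an estimated correlation.

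With all libraries and the default settings, lists for the response to bacteria did not pass. Interferon-stimulated genes had a median of 0.29, with 35 of 53 above 0 (camera adjusted p = 0.0934), and the members with the smallest p were Gbp5 at 1.02 (SE 0.38) and Ifit2 at 1.29 (SE 0.54). Pathogen sensing and inflammasome genes had 0.26 over 30 (camera adjusted p = 0.107), with Cgas, the cytosolic DNA sensor, at 1.20 (SE 0.36) and Casp4 at 3.46 (SE 1.21). NF-kappaB targets and inflammatory cytokines had -0.21 over 43 (camera adjusted p = 0.188), -0.10 with library totals and -0.35 after the GC and length correction, with Nfkb2 at -1.02 (SE 0.28) and Nfkbie at -0.93 (SE 0.29). Antigen presentation genes had -0.37 over 19 (camera adjusted p = 0.0628), with H2-D1 at -1.47 (SE 0.50) and H2-Q4 at -1.06 (SE 0.40), which share sequence with related class I genes. Listerial entry and adhesion receptors had -0.27 over 19 (camera adjusted p = 0.0536), with Cdh1, encoding E-cadherin, at -0.89 (SE 0.27) and Itga5 at -0.68 (SE 0.23). The list of listerial entry and adhesion receptors passed camera as lower without infected replicate 1 (-0.27), infected replicate 3 (-0.51), uninfected replicate 2 (-0.40) or uninfected replicate 3 (-0.40), after the GC and length correction (-0.45) and with no count filter (-0.29). It did not pass without uninfected replicate 1, where its median turned to 0.0098, or infected replicate 2 (-0.17), with library totals (-0.13) or among genes at least 5 times above the olfactory receptor level (-0.12). The antigen presentation list passed as lower without uninfected replicate 2 (-0.15) and with no filter (-0.38) but not after the GC and length correction (-0.076). Interferon-stimulated genes passed as higher with a stricter filter (0.30) but not without uninfected replicate 1 (0.13) or after that correction (0.082). The list of pathogen sensing and inflammasome genes passed as higher after it (0.12) but not among genes above that level (0.035).

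The lists of trophoblast stem cell markers, vesicle markers, imprinted genes, the cell cycle and cholesterol synthesis did not pass with those settings either. Trophoblast stem cell markers had a median of -0.21 over 21 genes (camera adjusted p = 0.0974), with Sox21 at -0.90 (SE 0.35) and Tfap2c at -0.55 (SE 0.30). Vesicle markers and biogenesis genes had -0.16 over 51 (camera adjusted p = 0.0740), with Arf6, which has a separate entry not joined to it, at -1.30 (SE 0.35) and Flot1 at -1.26 (SE 0.36), and adjusted over the list alone 3 passed higher and 5 lower. Imprinted and placental genes had -0.14 over 33 (camera adjusted p = 0.0974), with Rhox5 at -1.79 (SE 0.45) and Igf2 at -1.48 (SE 0.42). Cell cycle genes had -0.029 over 42 (camera adjusted p = 0.107), -0.16 to -0.011 with single libraries left out and 0.086 with library totals, with Gins2 at -1.37 (SE 0.38) and Cdk4 at -1.11 (SE 0.32). Cholesterol synthesis genes had -0.18 over 24 (camera adjusted p = 0.226), with Mvd at -1.06 (SE 0.36) and Msmo1 at 0.84 (SE 0.44). Vesicle markers and biogenesis (-0.38), imprinted and placental genes (-0.33) and trophoblast stem cell markers (-0.31) passed camera as lower without infected replicate 3, as did vesicle markers without uninfected replicate 2 (-0.27) or 3 (-0.22) and imprinted genes without uninfected replicate 3 (-0.17). After the GC and length correction the cell cycle list passed as lower at -0.28 and imprinted and placental genes at -0.20, and the list of vesicle markers and biogenesis passed at -0.16 with no count filter. None of these 5 lists passed among genes at least 5 times above the olfactory receptor level, where medians were -0.038 for trophoblast stem cell markers, -0.034 for vesicle markers, -0.24 for imprinted genes, -0.23 for cell cycle and -0.059 for cholesterol synthesis. None passed with library totals either, where the medians were, in the same order, -0.10, -0.035, -0.026, 0.086 and -0.062. The median of trophoblast stem cell markers was -0.088 without infected replicate 2 and -0.11 after the GC and length correction, not passing.

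Fibroblast, leukocyte, erythroid and embryonic stem cell markers gave no passing list with all libraries and the default settings. Fibroblast markers had a median of 0.026 over 30 genes (camera adjusted p = 0.721), with Col5a2 at 1.84 (SE 0.50) and Fap at 2.23 (SE 0.64). Macrophage and leukocyte markers had a median of -0.087 and a mean of 0.029 over 23 (camera direction lower, adjusted p = 0.935). Their median was 0.025 with library totals and from -0.18 to 0.15 with single libraries left out, with C1qc at -1.77 (SE 0.59) and Ctss at 1.43 (SE 0.66). The erythroid markers had -0.56 over 5 (camera adjusted p = 0.478), turning to 0.18 without uninfected replicate 3 and 0.15 with no filter, with Slc4a1 at -0.60 (SE 0.24) and Hba-x at -0.63 (SE 0.32). Embryonic stem cell and endoderm markers had -0.17 over 22 (camera adjusted p = 0.263), with Dab2 at 1.26 (SE 0.35) and Klf4 at -1.19 (SE 0.36). The list of fibroblast markers passed camera as higher after the GC and length correction, at 0.20, and had -0.028, not passing, among genes at least 5 times above the olfactory receptor level.

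Noncoding and mitochondrial transcripts varied between libraries. Small structured noncoding RNAs had a median of 0.014 and a mean of -0.36 over 29 genes, and camera placed them lower without passing (adjusted p = 0.0844), with Rn7sk at -1.93 (SE 0.54) and Rpph1 at -1.97 (SE 0.56). Nuclear-retained long noncoding RNAs had -0.16 over 9 (camera adjusted p = 0.511), -0.32 to 0.068 with single libraries left out, with Malat1 at -2.06 (SE 0.48) and Xist at 1.25 (SE 0.31), and adjusted over the list alone 1 passed higher and 1 lower. Mitochondrially encoded mRNAs had a median of 0.055 and a mean of 0.11 over 12, with camera's direction lower (adjusted p = 0.809), mt-Co1 at 0.97 (SE 0.61) and mt-Atp6 at -0.90 (SE 0.59). The mitochondrial rRNAs, a list of 2 genes too short to test, had mt-Rnr2 at -1.85 (SE 0.63) and mt-Rnr1 at -0.13 (SE 0.56), or 0.040 with library totals. The mitochondrially encoded mRNAs passed camera as lower without infected replicate 1, at -0.60, and after the GC and length correction, at -1.45, and had a median of 0.78 without uninfected replicate 1 and 0.41 among genes at least 5 times above the olfactory receptor level (passing in neither). The small structured noncoding RNAs passed in camera's lower direction with library totals, at a median of 0.10, with a stricter count filter, at -0.39, and after the GC and length correction, at -0.66, but turned to 0.27, not passing, with no filter.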

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

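The settings above background, the GC and length correction, and those leaving out 2 or 3 libraries were chosen after the results were seen. With edgeR, 0 genes changed with all libraries kept, under each setting run, with 872 to 3572 genes at an unadjusted p under 0.05, and DESeq2 called 213 (141 higher, 72 lower). Leaving out libraries gave 0 to 9 changed, 0 to 9 higher and 0 lower genes, with 126 to 4505 at an unadjusted p under 0.05. The 9 came from the fit without uninfected replicate 1 and infected replicates 1 and 2, in which 1 infected library is assumed to vary like the others. On counts simulated at the observed depth and spread, edgeR called 8.96% of genes of at least median level changed 2 times. The cause of the differences between settings was not tested, except that leaving out libraries leaves fewer samples. The setting above background also computed the TMM factors anew on the genes it kept.

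Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.0440, 0.0659 and -0.142, and uninfected replicate 1 correlated best with infected replicate 3. The replicate block gave 0 genes changed, 0 higher and 0 lower, 18 lists, and turned Peg10 from 0.031 to -0.78. The lists of listerial entry and adhesion receptors (-0.20), vesicle markers and biogenesis (-0.21) and small structured noncoding RNAs (-0.25) passed as lower with it, and differentiated trophoblast markers were 0.76.

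The count of lists, 15, was 22 (3 higher, 19 lower) after the GC and length correction, 18 with no filter, 18 with the replicate block, 16 with a stricter filter, 16 with library totals, 15 with DESeq2's size factors, 15 without mitochondrial genes, 0 with an estimated correlation, 0 with fry, 9 above background, 8 without infected replicates 1 and 2, 5 without uninfected replicate 1 and infected replicates 1 and 2, and 9 to 18 with single libraries left out. Single libraries left out gave differences of 904 to 1994 for genes detected, of -0.943 to 0.0476 percentage points for the 10 most abundant genes, of -0.228 to 0.143 for mitochondrially encoded genes and of -0.350 to -0.106 for ribosomal protein genes, and 0.00759 to 0.0741 for the correlation difference.

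List medians are given where camera's direction turned. Without uninfected replicate 1 and infected replicates 1 and 2 they were 0.22 for ribosomal proteins, 0.18 for translation factors, -0.056 for oxidative phosphorylation, 0.47 for heat shock, -0.0096 for actin, 0.15 for listerial receptors, 0.080 for vesicle markers, 0.10 for RNA-binding, 0.0067 for proteasome, -0.053 for imprinted, 0.056 for junctions, -0.30 for erythroid, -0.059 for embryonic stem cell, -0.31 for small RNAs and 0.11 for mitochondrial mRNAs. Those 3 libraries held the highest and the 2 lowest shares of ribosomal protein counts, so the turn of that list follows from the choice. Calls also ended for the lists of glycolysis (-0.16), endoplasmic reticulum stress and amino acid response (-0.17), immediate early genes (-0.32), p53 targets and apoptosis (-0.22) and autophagy and lysosome (-0.15) with them left out. Without infected replicates 1 and 2 the medians were 0.00046 for heat shock, -0.00051 for vesicle markers, 0.071 for fibroblast and 0.022 for macrophage markers, and calls ended for the lists of translation factors (-0.11), nuclear-encoded oxidative phosphorylation (-0.22), actin cytoskeleton (-0.094), RNA sorting and RNA-binding proteins (-0.15), autophagy and lysosome (-0.12), proteasome (-0.18) and epithelial keratins and junctions (-0.055). Single libraries left out gave -0.60 to 0.78 for mitochondrial mRNAs and -0.18 to 0.15 for macrophage markers. Mitochondrial mRNAs were 0.41 above background. Macrophage markers were -0.068 with the stricter filter, -0.0059 above background, 0.11 after GC correction and -0.087 with fry. The GC and length correction added calls for the lists of mitochondrially encoded mRNAs (-1.45), pathogen sensing and inflammasome (0.12), listerial entry and adhesion receptors (-0.45), cell cycle (-0.28), imprinted and placental genes (-0.20), fibroblast markers (0.20) and small structured noncoding RNAs (-0.66). Differentiated trophoblast markers were 0.012 above background, embryonic stem cell markers -0.15 after GC correction and small RNAs 0.27 with no filter.

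Log2 fold changes of named genes turned as follows. Without uninfected replicate 1 and infected replicates 1 and 2 they were 0.083 for Eif3f, 0.053 for Eef2, 0.0074 for mt-Rnr1, -0.28 for Ifit2, 0.11 for Tfap2c, 0.37 for 100861531, 0.34 for 667102, 0.79 for Ncl and 2.44 for Vaultrc5 (edgeR adjusted p = 6.86e-34, and at least 0.193 under the other settings, DESeq2 included). Without infected replicates 1 and 2 they were -0.42 for mt-Co1, -0.046 for Ifit2, 0.21 for 100861531, 0.23 for Vaultrc5 and 0.36 for Ncl. Single libraries left out gave -0.32 to 1.62 for mt-Co1, -1.61 to 0.10 for mt-Atp6, -1.11 to 0.61 for mt-Rnr1, -1.70 to 0.32 for mt-Nd6, -3.72 to 1.03 for Vaultrc5 and -1.92 to 0.86 for Peg10. After GC correction mt-Co1 was -0.46, Obscn 0.10 and Peg10 -0.11, and mt-Rnr1 was 0.040 with library totals and 0.25 above background.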

Other observations

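The tests of GC content and length on sensory receptors, ribosomal proteins and histones, of background reads on sensory receptors, of an exchange of libraries, and of other splits were chosen after the results they bear on were seen. Sensory receptor genes, listed after the data were seen, were counted higher in infected libraries. The median log2 fold change was 0.88 over 884 olfactory receptors, 722 of them above 0, 1.49 over 206 vomeronasal receptors and 1.15 over 24 taste receptors. Camera with the preset correlation gave adjusted p values of 1.51e-14, 2.17e-22 and 5.69e-05, and each had an adjusted p = 0.142 with an estimated correlation. Antigen receptor segments had a median of 0.48, and keratin-associated, beta-defensin and cornified envelope genes -0.065.

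Of DESeq2's 141 higher genes, 27 were sensory receptor genes, and of its 72 lower genes 0 were. The higher genes had a median GC content of 41.6% and the lower genes 55.3%, against 48.9% of all tested genes. Of the 173 tested entries named by symbol rather than by gene ID, 166 were among DESeq2's 213 calls. How these entries came to be named by symbol is not given in the sources used here, so the overlap cannot be taken as independent of the authors' own calls. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 213 DESeq2 genes and 3136 edgeR genes at unadjusted p under 0.05, the most of the 10 (1 of 10 splits each), and the highest of the others gave 107 and 2185. At the adjusted threshold edgeR gave 0 genes in all 10 splits. For lists, 3 of 10 splits gave at least the real count of 15, the highest other being 17.

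For the higher counts of sensory receptor genes, a larger share of reads that do not come from mature transcripts, such as genomic DNA, may contribute in infected libraries. In the same GC bins, genes under 2 times the olfactory receptor level deviated upward from genes at 5 times or more by 0.632 (SE 0.301), just over 2 standard errors. The genes under 2 times that level were not cleared of the sensory receptor genes themselves, so this value is not separate support. By library it was -0.838, -0.147 and 0.0598 in uninfected replicates 1 to 3 and 0.484, 0.422 and 0.0645 in infected replicates 1 to 3. GC content and length bias may account for part or all of the higher counts too. Correcting for both moved the olfactory receptor difference by -0.918 (SE 0.304), from 1.22 (SE 0.501) to 0.306 (SE 0.279). Both stay open, as does an effect of infection, which is untested.

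For the lower ribosomal protein and histone lists, dilution by background reads was set against 10000 random lists matched on level over background and GC. Exon length was not matched. Their medians lay from -0.359 to -0.0906 in 95% of lists for ribosomal proteins (observed -0.956) and from -0.536 to -0.262 for histones (observed -1.38). These random lists treat genes as independent, whereas the estimated correlation was 0.667 for ribosomal proteins and 0.198 for histones. Their range therefore leaves out spread that the genes share between libraries. The comparison cannot decide on dilution, which stays open for both lists. The GC and length trend that the correction removed is argued against as the whole account, because the correction moved the difference between groups by -0.136 (SE 0.0971) for ribosomal proteins, from -0.947 (SE 0.585) to -1.08 (SE 0.659), and by -0.00766 (SE 0.204) for histones, from -1.18 (SE 0.441) to -1.18 (SE 0.418). This measure of the shift was chosen after 2 others had been seen: whether the corrected difference lay beyond 2 standard errors, which it did for histones and not for ribosomal proteins, and whether the lists stayed past camera's preset threshold, which both did at medians of -1.17 and -1.23. The ribosomal protein difference lay within 2 standard errors of 0 before and after correction. Variation between single libraries stays open for cytosolic ribosomal proteins, the median being -0.49 without uninfected replicate 1 and -1.46 without infected replicate 3, as does an effect of infection for both lists, which is untested.

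Infected replicate 3 correlated more with uninfected replicates 2 and 3 than with infected replicates 1 and 2, by a gap of -0.0515. An exchange with an uninfected library is argued against only by correlations before GC and length correction. In these, each uninfected library correlated less with infected replicates 1 and 2 than with the other uninfected ones, the smallest difference being -0.0394. Splits that exchanged infected replicate 3 came nearest the real split in DESeq2 genes, though below it. They gave 107, 49 and 36 genes for uninfected replicates 3, 2 and 1, against 213. Their list counts were 15, 17 and 2, against 15. A wrong label on infected replicate 3 alone is not excluded by those correlations. GC content and length bias may account for most of the gap, which was -0.00436 after correction, still just below 0. That bias cannot be told apart from the other explanations. An effect of infection that differed between libraries is untested.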
